A study of Homo sapiens with 4 samples.

How the data were processed

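Total RNA of HEK293 cells, an established line of human embryonic kidney origin, was amplified to biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. Cells received 100 pmol of control or CDC73 siRNA, were moved 24 hours later to a 100 mm dish (sparse) or a 35 mm dish (confluent), and were harvested after 24 further hours. Each of the 4 groups, set by siRNA and density, had 1 array, and the labels number every array as replicate 1. They do not say whether the dishes came from separate transfections.

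The values used were those the authors deposited as a non-normalized table of probe intensity on a linear scale, per the file headers. It has no detection p-value, bead number or bead error, and the negative panel described below had median signals of 72.3 to 78.4, so background was taken as left in. The authors also deposited a log2 table of the same arrays with a median of 6.42 on each array, whose nearly equal quantiles show a normalization between arrays. Its correlation with log2 intensity was between 0.998 and 1.000 on the 4 arrays, so the scale and the direction are settled. The software and the steps that made both tables are not given in the sources used here, nor is a genome build, and no coordinates are printed.

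The tables listed 49576 probes, of which 773 had no value and 48803 had one on every array. Of these, 28098 probes had 1 gene symbol in the platform annotation, 13 had several and 20692 had none here. The 18852 distinct symbols were checked against RefSeq through Entrez numbers, and 39 probes had a number that the RefSeq table did not hold. Genes were named from probes with 1 symbol only. Total signal per array was 26276100 (control, sparse), 25283800 (CDC73, sparse), 28273400 (control, confluent) and 22948100 (CDC73, confluent).

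The plan had relied on detection p-values. In their absence, 452 probes of olfactory receptor genes, which HEK293 cells were taken not to express, served as the negative panel. The detection p of a probe was the share of panel probes with at least its signal on that array, and the panel was left out of all gene results. At a detection p under 0.01, between 28.0% and 30.5% of probes were detected on an array, with the limit at a signal between 103 and 123. Background was corrected by the normexp method of limma with the panel as negative controls, an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale. A gene took the value of its named probe with the highest mean over the 4 arrays. A gene was measured in a comparison when detected on at least 1 of its arrays.

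Differences between 2 arrays were described by size, with 2-fold (1 on the log2 scale) as the limit, and carry no p-value, since each group has 1 array. Where a named gene was detected on 1 side of a comparison only, a bound is given, taken against the higher of the detection limit and the dim probe's own value. Counts of genes and list medians use the values as they stand, also for such genes, unless a bound is stated. The number of arrays limits the precision. The only error available within the arrays was the disagreement between probes of a gene, taken from 1879 genes with 2 probes detected on all 4 arrays. For the 25 gene lists fixed before the data were examined (549 members, 513 named on the array), the median log2 difference was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A median stood apart when its percentile was under 2.5 or above 97.5. An additive limma fit of density and siRNA used all 4 arrays, with 1 residual degree of freedom and Benjamini-Hochberg adjustment.

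The lists were the PAF1 complex, YAP/TAZ targets, Hippo pathway components, Wnt/beta-catenin targets, Hedgehog targets, Notch targets, MYC and immediate early genes, p53 targets, G1/S genes, G2/M genes, replication-dependent histones, cholesterol synthesis, glycolysis and hypoxia, amino acid and ER stress, heat shock, interferon response, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, adhesion and junctions, extracellular matrix and cytoskeleton, neuronal markers, kidney and adrenal markers, fibroblast and haematopoietic markers, and apoptosis regulators. Named genes followed a rule also fixed before the data were examined. It took CDC73, the 8 measured genes with the largest difference in each direction where both sides were detected, at most 3 bounds per direction, and up to 4 members of each list with the largest difference. For the difference of the siRNA effects it took the 6 largest in each direction, and for agreement over the densities the 8 in each direction with the largest smaller effect, in both cases among genes detected on all 4 arrays. Provisional symbols were counted and not named.

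The alternatives were no background correction, an offset of 50, median scaling of the arrays, the authors' log2 table, a detection p under 0.05, no detection filter, detection on every array compared, the mean of all probes of a gene, and, for the additive fit, a trended and robust prior. A background fit by maximum likelihood without the panel, and detection set from the lower part of each array's signals, were added after seeing the data.

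The additive fit was tested on simulated data for the CDC73 siRNA term, with 10763 genes, 200 of them changed and a noise SD of 0.279 per array. It recovered 60% of 2-fold and 100% of 4-fold changes with 9 false calls. On the sparse pair of the same simulated arrays, the 2-fold size rule kept 47% of 2-fold and 99% of 4-fold changes and took 123 unchanged genes. These simulated arrays had the same noise SD for every gene and the same change at both densities, as the fit assumes. The shares recovered and the false calls therefore do not give the error rates on the real arrays. The percentile was tested on 10000 simulated genes: 7.5% of 200 unchanged lists of 20 genes fell outside the limits, and 98% of 50 lists shifted by 0.5 stood apart. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.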

Results

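Expression was measured in HEK293 cells given control siRNA or siRNA against CDC73, and plated so that they were sparse or confluent at harvest. CDC73 codes for parafibromin, a subunit of the PAF1 complex, which travels with RNA polymerase II during transcription. The layout crosses 2 siRNAs with 2 densities, with 1 array in each of the 4 groups. No difference therefore has a replicate check, and all values below describe single arrays. At a detection p under 0.01, 13680 probes were detected on the control sparse array, 14790 on the CDC73 sparse array, 14791 on the control confluent array and 14899 on the CDC73 confluent array. Over 10763 genes, the correlation between arrays lay between 0.954 (control sparse and CDC73 confluent) and 0.979 (control and CDC73 siRNA, both sparse).

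The knockdown could not be checked on these arrays. The only named CDC73 probe was not detected on any array at a detection p under 0.01, with signals of 72.3 (control) and 83.5 (CDC73 siRNA) in sparse cells and 98.4 (control) and 90.1 (CDC73 siRNA) in confluent cells. At a detection p under 0.05 it was detected on 1 array, that of confluent cells with control siRNA. No fold is given for it, and the siRNA groups below rest on the labels. The other subunits of the complex were measured. After CDC73 siRNA the log2 difference was 0.17 for PAF1, -0.34 for LEO1, 0.62 for RTF1 and -0.12 for SKIC8 (WDR61) in sparse cells, and 0.21, -0.20, 0.56 and -0.24 in confluent cells. CTR9 had probes that disagreed in sign, at 0.37 and -0.32 in sparse cells. A second LEO1 probe, detected on the array of confluent cells with CDC73 siRNA only, was at 0.61 in confluent cells, opposite to the brighter one. The list median was 0.17 in sparse and 0.21 in confluent cells and did not stand apart.

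In sparse cells, targets of the stress-activated factor p53 and genes of the replication-dependent histones were higher with CDC73 siRNA. The p53 target TP53I3, a quinone oxidoreductase, was 5.75-fold higher, and GDF15, a secreted stress cytokine, was higher by 1.63 on the log2 scale. Of 19 measured p53 targets 17 were higher, 7 of them at least 2-fold by values not set to a bound, with a median of 0.74 at the 100th percentile of random lists. Of 15 measured histone genes 14 were higher, 5 at least 2-fold, with a median of 0.82, also at the 100th percentile. Among them H2BC5 was higher by 1.73, H2AC6 by 1.58 and H2BC12 by 1.32. With undetected control values set to the detection limit, the medians were 0.52 for p53 targets and 0.54 for histones. Without a detection filter they were 0.47 and 0.50, and the histone median was 0.50 without background correction and 0.51 in the authors' log2 table.

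Other genes with large differences in sparse cells had varied functions. Higher were ACTA2, a smooth muscle actin (2.11), TMEM145 (1.89), TNFRSF14, a TNF receptor family member (1.83), EMP1 (1.71), the heat shock chaperone HSPA1A (1.69) and the zinc transporter SLC30A3 (1.64). Lower were HIRIP3, named for its binding to the histone chaperone HIRA (-2.79), the proteasome subunit PSMA2 (-2.14), DEGS1, a desaturase of ceramide synthesis (-2.08), the isocitrate dehydrogenase IDH1 (-2.0), TMEM123 (-1.97), the adenylate kinase AK3 (-1.90), GATC (-1.90) and CBFB, the partner of RUNX factors (-1.89). MYBPHL was at least 3.53-fold, CGA at least 2.65-fold and ETV4 at least 2.62-fold higher, being undetected with control siRNA. RFK was at least 3.07-fold, NUS1 at least 2.80-fold and IL37 at least 2.77-fold lower.

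Smaller shifts of whole lists were also present in sparse cells. The amino acid and ER stress list had a median of 0.26 (percentile 99.8), led by the ER chaperone HSPA5 at 1.45, and PDIA4, a disulfide isomerase of the ER, was at 1.01. G2/M genes had a median of -0.17 (percentile 0.680), with 20 of 28 lower and none 2-fold, and median scaling, which raised all genes, gave -0.0115 (percentile 0.830). G1/S genes had a median of 0.19 (percentile 98.0), with 16 of 21 higher and none 2-fold, were at 0.35 with median scaling, and fell back within the limits when the detection limit was relaxed, dropped or probes were averaged. Cytosolic ribosomal proteins had a median of -0.11 (percentile 1.47), with RPL14 at -1.02, and the extracellular matrix and cytoskeleton list one of 0.25 (percentile 98.7). The latter held ACTA2 as well as TAGLN, another smooth muscle protein, at -1.26, and 5 of 10 alternatives took its median within the limits, at 0.10 without a detection filter and 0.16 with a detection p under 0.05 or over genes detected on both arrays. For ribosomal proteins 3 alternatives did so, with a median of -0.046 in the authors' log2 table (-0.04 with median scaling, still outside), and for amino acid and ER stress the authors' log2 table did, at 0.17.

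In all, 216 genes were at least 2-fold higher and 182 at least 2-fold lower in sparse cells among 10182 measured. With genes undetected on 1 side set to their bound, these counts were 111 and 153. With median scaling the split was 470 higher and 92 lower, as the median of all genes moved up by 0.19. It was 30 and 57 without background correction, 57 and 96 with an offset of 50, 40 and 74 in the authors' log2 table, 94 and 122 with background by maximum likelihood and 93 and 137 among genes detected on both arrays, so the balance of directions was not settled. The disagreement between 2 probes of a gene gave a probe SD of 0.252. Here and below this is an SD per probe, the SD of the difference between the probes divided by the square root of 2. Of 41 genes whose brighter probe passed 2-fold, 37 had a second probe of the same sign and 16 a second probe past 2-fold.

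In confluent cells, CDC73 siRNA was again accompanied by higher p53 targets and histones, while G1/S and G2/M genes were mostly lower. TP53I3 was 8.10-fold higher and GDF15 higher by 1.91. BAX, a pro-apoptotic BCL2 family member, was at 1.12 and TIGAR, a phosphatase of the glycolytic branch, at 1.03. Of 19 measured p53 targets 14 were higher, 4 at least 2-fold, with a median of 0.54 at the 100th percentile. Of 16 histone genes 14 were higher, 5 at least 2-fold, with a median of 0.82 at the 100th percentile, and H2BC5 was at 2.86, H2AC6 at 1.91, the linker histone H1-2 at 1.64 and H4C8 at 1.36. Without background correction the p53 median was 0.34.

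In confluent cells G1/S genes had a median of -0.29 (percentile 0.340), with 14 of 22 lower, and G2/M genes one of -0.25 (percentile 0.990), with 23 of 28 lower. The transcription factor E2F2 was at -1.57, UHRF1, a factor for maintenance of DNA methylation, at -1.05, the kinetochore motor CENPE at -1.04 and TOP2A, a DNA topoisomerase, at -0.94. Without a detection filter the G1/S median was -0.12, at a percentile of 8.30 and within the limits, and it was -0.13 with median scaling and -0.46 over genes detected on both arrays. Outside these lists, the D-type cyclin CCND1, which drives passage through G1, was at -2.62 and CCND2 at -2.07.

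YAP/TAZ targets, which respond to cell contact through the Hippo pathway, had a median of 0.45 in confluent cells at the 100th percentile, with 13 of 21 higher and none 2-fold. ANKRD1 was at 0.99, MYOF at 0.77 and CCN1 (CYR61) at 0.68. The call rested on dim members, for the median was 0.020 at a percentile of 56.4 over the genes detected on both arrays and 0.0087 at a percentile of 58.1 without a detection filter. It was 0.28 with undetected values set to their bound, 0.22 without background correction, 0.28 with an offset of 50 and 0.25 in the authors' log2 table.

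The other leading genes of the confluent comparison were EGR1, an immediate early transcription factor (3.04), MYBPHL (2.90), CELP, a pseudogene of CEL that can share its probe target (2.22), SUGCT (2.10) and CYGB, a globin (2.04). Lower were TMEM123 (-2.59), TRIP13, an ATPase of meiotic and spindle checkpoint proteins (-2.49), the cyclin CCNY (-2.40), the secreted protein DKK3 (-2.36), HIRIP3 (-2.34), the ER chaperone CLGN (-2.25) and CBFB (-2.25). CLCA2 was at least 4.93-fold, DNAI3 at least 4.07-fold and DNAI7 at least 4.0-fold higher. CAPN5 was at least 3.89-fold, TMPO at least 3.39-fold and GATC at least 3.20-fold lower. In all, 239 genes were at least 2-fold higher and 364 at least 2-fold lower among 10497 measured. With median scaling these were 371 and 243, while without background correction they were 75 and 128. The probe SD was 0.327, and 87 of 97 second probes had the same sign, of which 36 passed 2-fold.

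The effects of CDC73 siRNA at the 2 densities come from separate arrays, but the labels do not say whether from separate transfections. With the knockdown unchecked, an effect shared by the densities is one of the siRNA as labelled. Whether it came from loss of CDC73 or from other targets of the siRNA was not tested. The siRNA effects correlated across 10763 genes with r = 0.35 and rho = 0.25, genes not being independent replicates. Among 9916 genes measured in both, 43 were at least 2-fold higher at both densities against 3.69 expected for independent lists, and 77 were lower at both against 6.0. Among the 9047 genes detected on all 4 arrays these counts were 19 and 65. Opposite 2-fold effects occurred for 1 gene that was higher and 1 gene that was lower in sparse cells. The genes with the largest effect at both densities were, on the higher side, TP53I3, H2BC5, GDF15, H2AC6, HSPA5 (1.45 sparse and 1.68 confluent), TMEM145 (1.89 and 1.24), the antiviral membrane protein BST2 (1.19 and 1.34) and EMP1 (1.71 and 1.18). On the lower side they were HIRIP3, DEGS1 (-2.08 and -2.06), IDH1 (-2.0 and -2.13), TMEM123, CBFB, PSMA2 (-2.14 and -1.84), CNIH1 (-1.81 and -2.18) and DKK3 (-1.80 and -2.36). A second probe had the same sign for H2BC5 at both densities, for DEGS1 and IDH1 in sparse cells and for DKK3 in confluent cells. Second probes were looked up only in a comparison of arrays in which the gene was named. Those of DEGS1 and IDH1 in confluent cells and of DKK3 in sparse cells were therefore not examined.

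**Figure D1:**
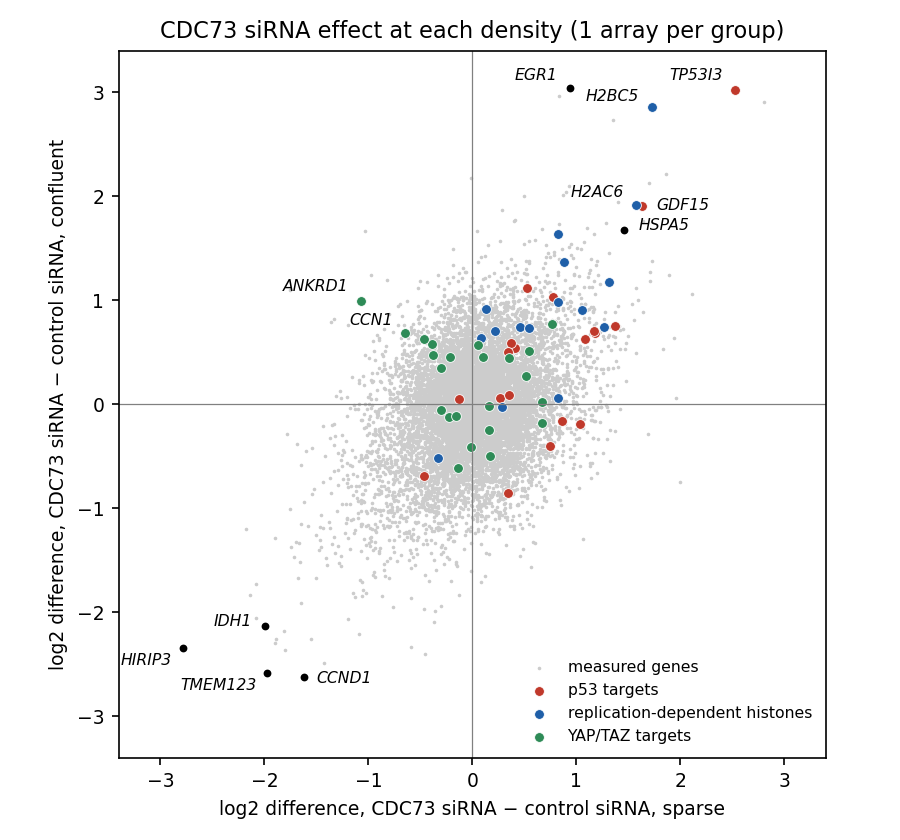
Log2 difference between the CDC73 siRNA and the control siRNA array in sparse cells (horizontal) and in confluent cells (vertical), with 1 point per measured gene, gene lists in colour and selected named genes in italics. TP53I3 lies at 2.52 and 3.02 and HIRIP3 at -2.79 and -2.34, while ANKRD1 lies at -1.07 and 0.99.

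With control siRNA, confluent cells had lower YAP/TAZ targets, ribosome biogenesis genes and heat shock genes than sparse cells, and higher p53 targets. The YAP/TAZ targets ANKRD1, CCN2 (CTGF) and CCN1 were at -2.95, -2.49 and -2.29. Of 19 measured YAP/TAZ targets 14 were lower, 5 at least 2-fold, with a median of -0.53, below all 10000 random lists. Ribosome biogenesis genes had a median of -0.71, below all random lists, with 19 of 20 lower and 6 at least 2-fold, among them NOP16 at -2.16, RRS1 at -1.45 and PPAN at -1.10. Heat shock genes had a median of -0.54, below all random lists, with 12 of 13 lower, HSPH1 at -1.45 and CHORDC1 at -1.36. Of 18 p53 targets 17 were higher, 7 at least 2-fold, with a median of 0.81 at the 100th percentile. CDKN1A, the cyclin-dependent kinase inhibitor p21, was at 2.07, GDF15 at 1.68, SPATA18 at 1.47 and TP53INP1 at 1.39. The YAP/TAZ median was -0.27 with median scaling and -0.30 without a detection filter.

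Further lists that stood apart with density under control siRNA were Notch targets (median 0.37, percentile 98.5), with HES5 at 1.74, NOTCH3 at 1.22 and HEY1 at 1.02, and the interferon response (0.44, percentile 99.5), with BST2 at 1.3 and IRF9 at 1.1. Cholesterol synthesis had a median of -0.34 (percentile 0.310), with SQLE at -0.96 and HMGCS1 at -0.79, while TM7SF2 was at 1.04, and median scaling gave -0.17. G2/M genes had a median of -0.24 (percentile 0.560), with 22 of 28 lower. Replication-dependent histones had a median of 0.35 (percentile 98.5) and the PAF1 complex one of -0.44 (percentile 2.44) with all 5 measured subunits lower. These latter calls held in 6 and in 5 of 11 settings, and the histone median was 0.20 without a detection filter, 0.21 without background correction and 0.22 in the authors' log2 table.

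The genes with the largest density differences under control siRNA were CEL, a lipase (2.79), TNFRSF14 (2.56), IGFBP5, an IGF-binding protein (2.55), ZNF467 (2.53), ATP6V1G2 (2.46), PARM1 (2.45), TXNIP, a thioredoxin-binding protein (2.37) and the lipocalin APOD (2.21). Lower, beside YAP/TAZ targets and NOP16, were TNFRSF12A (-2.39), the ETS factor ETV5 (-2.06), the pseudogene ANP32AP1, which can share signal with its parent (-1.98), and MIX23 (-1.82). ADHFE1 was at least 4.23-fold, FAXDC2 at least 3.45-fold and CACNG6 at least 2.97-fold higher, and TFPI2 at least 3.15-fold, CPA4 at least 2.36-fold and NRG1 at least 2.33-fold lower. In all, 395 genes were at least 2-fold higher and 168 at least 2-fold lower among 10244 measured. With median scaling, which moved the median of all genes by 0.15, the split was 725 and 98. The probe SD was 0.279, and 48 of 55 second probes had the same sign, of which 22 passed 2-fold.

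With CDC73 siRNA, confluent cells again had lower ribosome biogenesis, heat shock and YAP/TAZ genes than sparse cells, and G1/S and G2/M genes were mostly lower too. Ribosome biogenesis genes had a median of -0.90, below all random lists, with 19 of 21 lower and 10 at least 2-fold, among them BOP1 at -1.59, NOLC1 at -1.53 and NOP2 at -1.53. Heat shock genes had a median of -0.89, below all random lists, with HSPA1A at -1.99. HSPA1B, nearly identical to it, was at -1.83, and probes may not separate this pair. YAP/TAZ targets had a median of -0.40 (percentile 0.370), with 15 of 23 lower, CCN2 at -2.89, GADD45B at -1.73 and FJX1 at -1.37. The authors' log2 table took that list within the limits, at -0.21 and a percentile of 2.89, and without background correction it was at -0.23.

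G1/S genes had a median of -0.56 (percentile 0.01), with 17 of 22 lower, and G2/M genes one of -0.51, below all random lists, with 21 of 28 lower. UHRF1 was at -1.0, RRM2, a ribonucleotide reductase subunit, at -0.83, BIRC5 at -1.08 and the mitotic kinesin KIF20A at -1.0. Of 19 p53 targets 14 were higher, with a median of 0.61 at the 100th percentile, GDF15 at 1.96, TP53INP1 at 1.57 and DDB2 at 1.38. Replication-dependent histones had a median of 0.52 (percentile 99.8), with H1-2 at 1.73 and H2BC5 at 1.17. The interferon response had a median of 0.51 (percentile 99.8), with BST2 at 1.46 and IFIT1 at 0.93. Fibroblast and haematopoietic markers had a median of 0.60 (percentile 97.7) over 5 measured genes, with PDGFRA at 0.78, and stood apart in 3 of 11 settings, with medians of 0.30 without background correction, 0.22 in the authors' log2 table and -0.0014 without a detection filter. The p53 median was 0.35 with averaged probes, the histone median 0.30 without background correction and 0.32 in the authors' log2 table, and the interferon median 0.26 without a detection filter.

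The leading genes with density under CDC73 siRNA were CYP3A5, a cytochrome P450 (3.57), APOD (3.0), TMT1A (2.91), YPEL3 (2.86), the aldo-keto reductase AKR1C3 (2.47), the interferon-inducible GTPase GBP2 (2.42), NREP (2.38) and the cholesterol exporter ABCA1 (2.27). Lower were CCN2, the amino acid transporter SLC7A5 (-2.45), LETM1 (-2.35), GPRC5A (-2.17), ETV5 (-2.05), the folate enzyme MTHFD1L (-2.01), HSPA1A and IFRD2 (-1.99). INPP5D was at least 5.16-fold, CLCA2 at least 4.93-fold and IFI44L at least 4.42-fold higher, and TRAF3 at least 3.90-fold, ETV4 at least 3.28-fold and B4GALNT1 at least 3.23-fold lower. In all, 453 genes were at least 2-fold higher and 408 at least 2-fold lower among 10509 measured, against 569 and 328 with median scaling. The probe SD was 0.324, and 88 of 94 second probes had the same sign, of which 39 passed 2-fold.

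The density effects under both siRNAs, which share no array, correlated across 10763 genes with r = 0.48 and rho = 0.42. Among 9990 genes, 142 were at least 2-fold higher in confluent cells under both siRNAs against 14.7 expected for independent lists, and 57 were lower under both against 5.93.

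**Figure D2:**
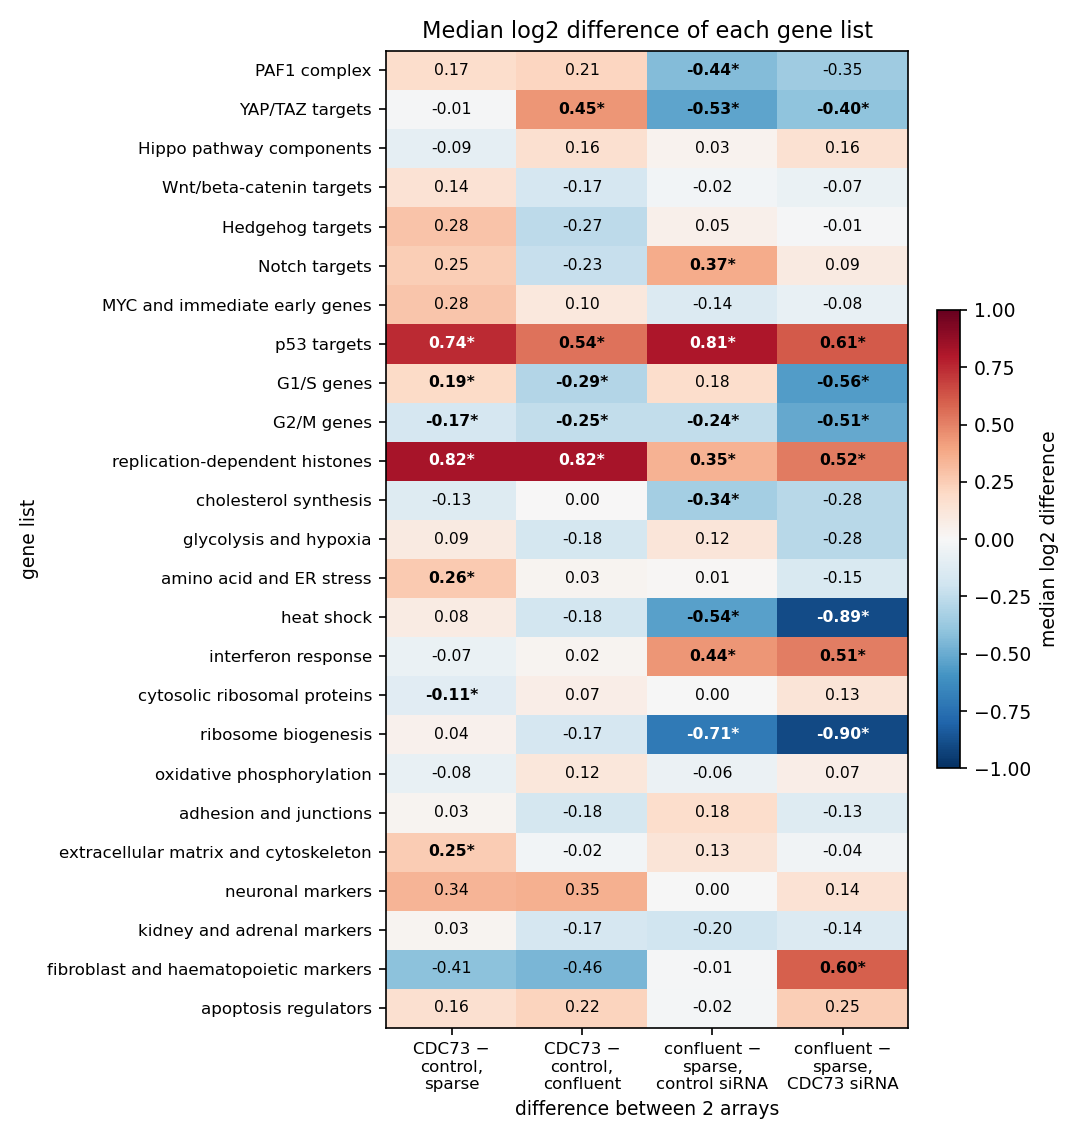
Median log2 difference of each of the 25 gene lists (vertical) in the 4 comparisons of single arrays (horizontal), in colour and as printed values. An asterisk marks a list that stood apart from random lists, as for p53 targets, at 0.74, 0.54, 0.81 and 0.61 from left to right.

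Of the 100 list medians in these 4 comparisons, 31 stood apart. The limits give 5 by chance, while the 7.5% of unchanged simulated lists outside them would give 7.5. Each array enters 2 of these comparisons, so they are not independent. Both chance figures also take the genes of a list as varying independently. They do not say how many lists of genes that vary together would stand apart between 2 like cultures. Lists that stood apart in no comparison of arrays had medians between -0.09 and 0.16 (Hippo pathway components), -0.17 and 0.14 (Wnt/beta-catenin targets), -0.27 and 0.28 (Hedgehog targets), -0.14 and 0.28 (MYC and immediate early genes), -0.28 and 0.12 (glycolysis and hypoxia), -0.08 and 0.12 (oxidative phosphorylation), -0.18 and 0.18 (adhesion and junctions), -0.0048 and 0.35 (neuronal markers), -0.20 and 0.03 (kidney and adrenal markers) and -0.02 and 0.25 (apoptosis regulators).

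The difference between the siRNA effects at the 2 densities has no residual degrees of freedom, and is described by size. It was largest on the higher side, where CDC73 siRNA acted more upward in confluent cells, for KLF5, a zinc finger transcription factor (2.15), EGR1 (2.11), ANKRD1 (2.06), EAPP (2.03), ANP32AP1 (1.95) and TXNL1 (1.69). On the lower side were HSPA1A (-1.98), CCNY (-1.94), ZFC3H1 (-1.86), the histone demethylase KDM3A (-1.74), NBPF9, of a family of near-identical copies (-1.72), and SCARF2 (-1.70). Among lists, G1/S genes had a median of -0.56 (percentile 0.0200), with 17 of 22 lower, and G2/M genes one of -0.36 (percentile 0.400). Hedgehog targets were at -0.66 (percentile 0.645), Notch targets at -0.57 (percentile 0.310) and oxidative phosphorylation at 0.29 (percentile 99.9). The Notch call ended without a detection filter (-0.35), and the G2/M call with median scaling (-0.32) and with averaged probes (-0.21). Hedgehog targets were at -0.31 without background correction, -0.44 with an offset of 50 and -0.33 in the authors' log2 table, and oxidative phosphorylation was at 0.46 with median scaling. In all, 312 genes were at least 2-fold higher and 499 at least 2-fold lower among 10763, or 233 and 643 with median scaling. The probe SD was 0.375, and of 78 genes past 2-fold 64 had a second probe of the same sign, but only 10 had one past 2-fold in the same direction.

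The additive fit takes the part of each effect that differs between the densities as the error. With limma it gave 443 genes for CDC73 siRNA, 189 higher and 254 lower, and 869 for density, 536 higher and 333 lower, at an adjusted p under 0.05 among 10763 genes. With median scaling these splits were 307 and 126, and 764 and 177. The fit set the same standard error of 0.281 for every gene, since its prior outweighed the 1 residual degree of freedom, so it acted as a limit on fold size. Without a detection filter limma called 0 genes for either term, with 1963 (CDC73 siRNA) and 2775 (density) at an unadjusted p under 0.05.

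**Figure D3:**
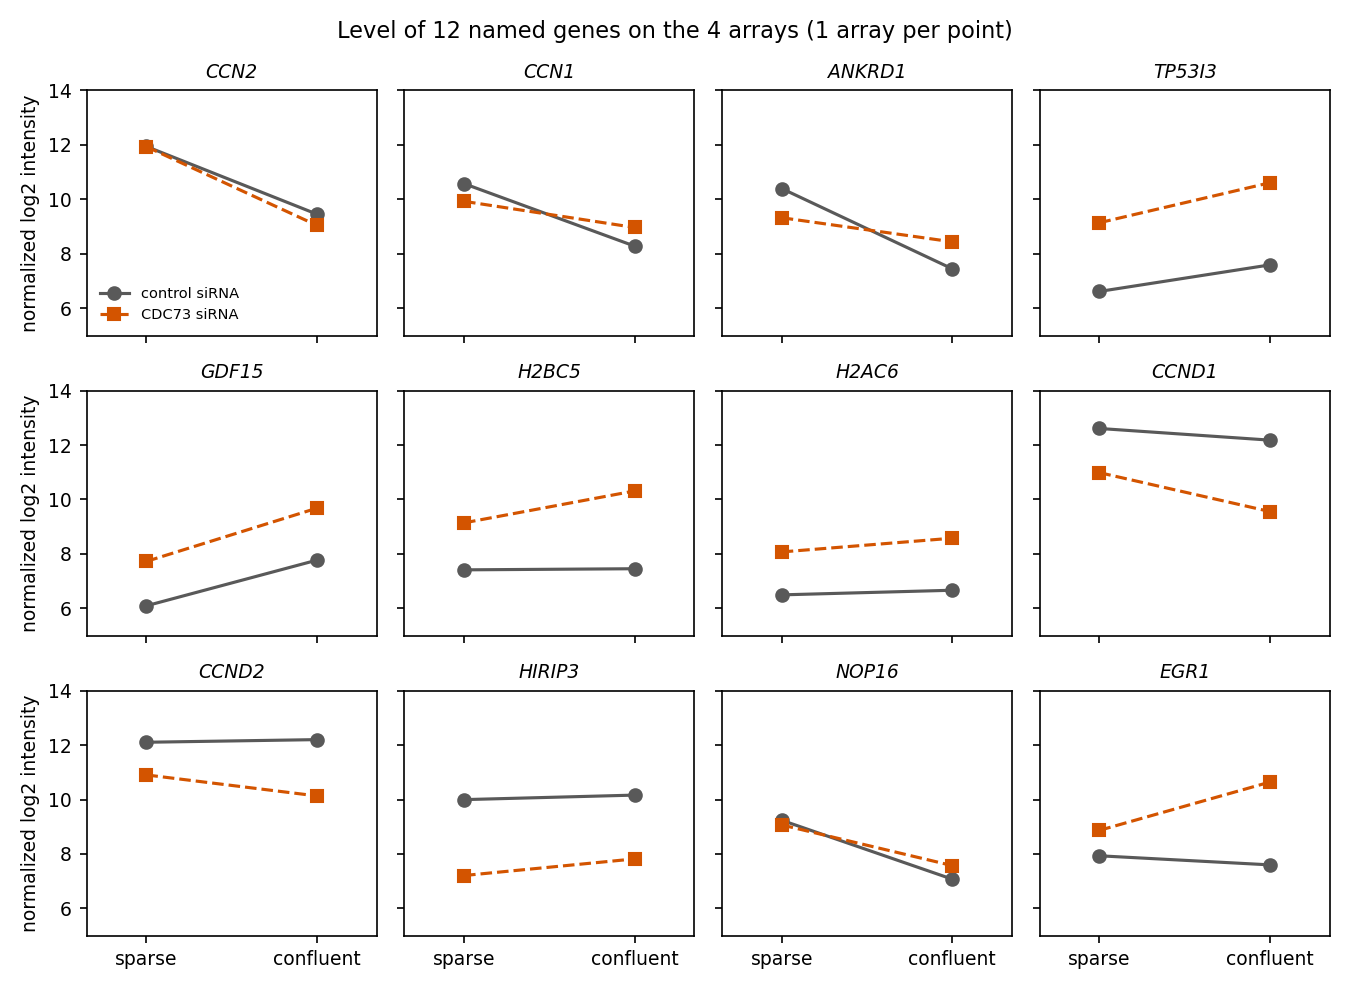
Normalized log2 intensity (vertical) of 12 named genes in sparse and confluent cells (horizontal), with circles for control siRNA and squares for CDC73 siRNA and 1 array per point. CCN2 lies lower in confluent cells under both siRNAs, by -2.49 and -2.89 on the log2 scale, and H2BC5 lies higher with CDC73 siRNA at both densities.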

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

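All tests in this part were chosen after the results they bear on had been seen, and each difference below compares single arrays and was not tested. Among named genes detected on all 4 arrays, CDC73 siRNA went at least 1.5-fold in opposite directions at the 2 densities for 7. The effect in confluent minus that in sparse cells was 2.15 for KLF5, 2.06 for ANKRD1 (-1.07 sparse and 0.99 confluent), 2.03 for EAPP, 1.95 for ANP32AP1, 1.33 for CCN1 (-0.65 and 0.68), -1.28 for KIF20A and -1.86 for ZFC3H1. ANKRD1 and CCN1 do not stand for the YAP/TAZ list, whose median for this difference was 0.09 (percentile 84.1, 14 of 23 higher) and did not stand apart. In sparse cells the list median with CDC73 siRNA was -0.0091 (percentile 23.1), also within the limits. For 3 named genes, again among those detected on all 4 arrays, density went in opposite directions under the siRNAs. The density effect under CDC73 siRNA minus that under control siRNA was -1.94 for CCNY (0.92 under control), -1.74 for KDM3A (1.15) and 1.69 for TXNL1 (-0.91). Among 9047 genes detected on all 4 arrays, 33 had such opposite siRNA effects against 458 of the same sign, and 26 had opposite density effects.

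Replication-dependent histones were higher with CDC73 siRNA at both densities. The list median was at the 100th percentile at both densities in all 11 settings, which argues against normalization, background correction or the detection filter as the whole cause. Its size did depend on them: a bound of 0.5 above the median of all genes, the first one tried, was missed at 0.47 in the lowest setting (highest 0.97), and the percentile was taken up after that. A rise confined to 1 histone family, as from cross-hybridisation within it alone, is argued against by medians of at least 0.5 at both densities in 4 of 5 families (H1 with 1 gene, and H4 the exception at 0.21 and 0.45). Cross-hybridisation between similar members inside each of several families could not be tested, as no probe sequences were at hand. The number of histone genes that were higher may therefore include shared signals. More cells in S phase were looked for through G1/S genes. Their median was -0.29 in confluent cells, or -0.12 at a percentile of 8.30 without a detection filter, so these genes showed no rise there. It was 0.19 in sparse cells. Levels of these transcripts do not measure the share of cells in S phase, so this explanation stays open at both densities.

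More genes were 2-fold apart after CDC73 siRNA in confluent (603) than in sparse cells (398). Larger noise of single probes alone is argued against by the covariance between probes of a gene. It was larger in confluent cells by 0.043 (0.0286 to 0.0583 in a bootstrap over genes, not arrays), although the probe SD was 1.3 times as large too. Noise shared by the probes of a gene would raise this covariance as well, so it stays open. Noise of dim probes is argued against by a ratio of 2.03 among the brightest genes. Normalization stays open, since the ratio fell to 1.09 with median scaling. A difference between single cultures or hybridisations cannot be told apart from the density either, with 1 array per group.

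Transcripts of mitochondrial ribosomal proteins, a group chosen after its values were seen, were lower on the control confluent array than on the arrays it was compared with. Their median was -0.48 in confluent against sparse cells with control siRNA (70 of 76 lower) and 0.30 with CDC73 against control siRNA in confluent cells (61 of 76 higher), comparisons that share that array. A loss of all nuclear-coded mitochondrial transcripts to that extent is argued against by oxidative phosphorylation genes at -0.06 (SD of members 0.263), but a smaller loss of these stays open, with 0.12 for CDC73 siRNA in confluent cells (19 of 29 higher, percentile 93.8) and 0.29 for the difference of the siRNA effects (percentile 99.9). In sparse cells CDC73 siRNA also went with a lower median, -0.14 (56 of 76 lower, percentile 0.02), so the CDC73 sparse array was low as well. With CDC73 siRNA the density difference was -0.03, which that low sparse array bears on, so the control confluent array or culture alone cannot be told apart from effects of density and siRNA.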

How the results depend on the processing

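Counts of 2-fold genes depended strongly on how dim signals were treated. Higher and lower counts are given for CDC73 siRNA in sparse cells, CDC73 siRNA in confluent cells, density under control siRNA, density under CDC73 siRNA, and the difference of the siRNA effects, in that order. Without background correction they were 30 and 57, 75 and 128, 108 and 52, 153 and 127, and 66 and 115. With an offset of 50 they were 57 and 96, 119 and 189, 180 and 77, 244 and 203, and 119 and 199. In the authors' log2 table they were 40 and 74, 97 and 166, 143 and 66, 195 and 172, and 91 and 151. With background by maximum likelihood, added after seeing the data, they were 94 and 122, 148 and 238, 246 and 108, 321 and 267, and 180 and 295. No background correction and a larger offset shrink the folds of dim genes by construction, while the cause of the lower counts in the other settings was not tested. With median scaling they were 470 and 92, 371 and 243, 725 and 98, 569 and 328, and 233 and 643. Over genes detected on every array compared, which by construction drops genes absent on 1 side, they were 93 and 137, 179 and 278, 234 and 133, 320 and 299, and 207 and 289. With genes undetected on 1 side set to their bound, the counts of the 4 comparisons of arrays were 111 and 153, 198 and 306, 265 and 142, and 356 and 332. A detection p under 0.05, no detection filter, averaged probes and detection from the lower part of each array moved none of these counts by over 1.5 times. CDC73 was detected on 1 confluent array at a detection p under 0.05, and on none at 0.01. Without a detection filter the additive limma fit called 0 genes for siRNA and 0 for density (unadjusted p under 0.05 in 1963 and 2775), as the dim genes brought the prior degrees of freedom down to 4.59, and in the other settings it called 397 to 477 and 772 to 950.

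Of 4777 recomputed log2 differences of named genes, 4236 moved by less than the probe spread, 541 moved by more, and 0 of those at least 2-fold changed sign. Of the 31 list medians that stood apart in comparisons of arrays, 18 moved by over 1.5 times in some setting, in 36 of 310 recomputed values, and 21 of these 36 still stood apart. With median scaling part of such moves is the shift of all genes. Of 1245 recomputed list medians, with the difference of the siRNA effects included, 1189 stayed on their side of the limits, 36 came within them, 19 went outside and 1 that stood apart changed sign, that of fibroblast and haematopoietic markers with density under CDC73 siRNA, at -0.0014 without a detection filter, and the cause was not tested. The p53 targets stood apart in all 4 comparisons and all 11 settings, as did ribosome biogenesis and heat shock with density. The comparisons share arrays and the settings reprocess the same 4 arrays, so these are not independent repeats. No paired analysis was possible because the groups share 1 replicate number only, so no fit with that number as a block exists. The additive fit does compare the siRNAs within each density, with density as a factor of the design and not as a pairing of cultures. Leaving out an array and other splits of the samples were not run, since leaving out an array removes its only group and ends the comparisons it enters. Signal over background limited CDC73 itself and every bound.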

Other observations

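The gene groups in this part, save cytosolic ribosomal proteins and replication-dependent histones, were chosen after their values were seen, as were the tests. Some further groups were lower in confluent than in sparse cells under both siRNAs, while ribosomal proteins were not under both. Aminoacyl-tRNA synthetases, which charge tRNAs, had a median of -0.41 (percentile 0.0300) with control and -0.49 (percentile 0.0700) with CDC73 siRNA, with 13 and 16 of 18 lower. Subunits of RNA polymerases I and III had medians of -0.49 and -0.44 over 15 genes. Proteasome subunits, with some assembly factors of the same gene names, were at -0.49 (30 of 31 lower) and -0.24 (25 of 31 lower). ETS variant factors, feedback genes of the ERK pathway and genes that respond to it, such as CCND1, were at -0.49 (7 of 8 lower) and -0.62 (10 of 10 lower), with ETV5 at -2.06 and -2.05. Cytosolic ribosomal proteins, in contrast, were at -0.0045 with control and 0.13 with CDC73 siRNA (22 of 27 higher), and mitochondrial ribosomal proteins were at -0.48 with control but -0.03 with CDC73 siRNA. Other groups tried were also lower under both, so a fall was not particular to those above. They included tubulins (-0.22 and -0.44), chaperonin CCT subunits (-0.29 and -0.57) and translation initiation factors (-0.15 and -0.22). The tubulin and initiation factor groups were taken by gene name and also held other proteins, such as TUBGCP2, and EIF2AK1 and EIF4EBP1. Zinc finger (ZNF) genes were at 0.17 and 0.05, and cyclin-dependent kinase inhibitors at 0.16 and 0.53. Relative to all genes, over all 11 settings, the medians with control and CDC73 siRNA lay between -0.58 and -0.40 and between -0.57 and -0.46 for synthetases, between -0.67 and -0.45 and between -0.23 and -0.18 for the proteasome group, and between -0.52 and -0.37 and between -0.60 and -0.33 for the ERK group, which in the last case moved by over 1.5 times.

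Among 3 D-type cyclins measured, CCND1 and CCND2 were lower with CDC73 siRNA at both densities, at -1.62 and -2.62 for CCND1 and -1.20 and -2.07 for CCND2, while CCND3 was at 0.18 in sparse and -0.74 in confluent cells. Subunits and accessory proteins of the vacuolar ATPase, the pump that acidifies lysosomes, had a median of -0.29 with CDC73 siRNA in confluent cells (percentile 1.00) and -0.12 in sparse cells (percentile 6.11). Nucleoporins were at -0.28 with CDC73 siRNA in confluent cells, with 16 of 21 lower, and at 0.08 in sparse cells.

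One hypothesis was that CDC73 siRNA raised all histone genes. Replication-independent histone variants, whose transcripts mostly carry a poly(A) tail, speak against it, with a median of 0.07 in sparse cells (SD of 11 members 0.480) and -0.15 in confluent cells (SD 0.586), against 0.82 and 0.82 for replication-dependent histones. Of these variants 6 were higher and 5 lower in sparse cells, 1 of them 2-fold lower. In confluent cells 3 were higher, 1 of them at least 2-fold, and 8 lower. The group includes CENPA, also a member of the G2/M list. Transcripts of replication-dependent histones normally end in a stem-loop with no poly(A) tail, and the amplification used for such arrays starts from poly(A). The higher signal may thus come from more histone transcripts or from a larger share of them with a poly(A) tail, and the arrays cannot separate these.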
